A study of Arabidopsis lyrata and Capsella rubella with 8 samples.

How the data were processed

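Small RNAs of *Arabidopsis lyrata*, an outcrossing perennial relative of *Arabidopsis thaliana*, were sequenced from strain MN47 in 2 tissues: flowers of stages 1 to 12 and whole seedlings aged 14 days, with 2 libraries of each. The series lists 8 samples; its 4 *Capsella rubella* samples were not analysed here. The labels do not say whether the libraries of a tissue came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

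Per the labels' protocols, small RNAs were size-selected from total RNA, joined to adaptors at each end, amplified by RT-PCR and sequenced. The sources disagree on the instrument: the sample protocols name a Roche FLX pyrosequencer and the series design text an Illumina Genome Analyzer. The design text also records computational removal of the 3′ adaptor. The deposited files hold raw read counts: each line is 1 match of a distinct small RNA sequence to the genome, with the number of reads of that sequence, repeated on every match. The aligner, the mismatch rule, the filters and the genome build were not given in the sources used here. Coordinates are therefore those of the deposited scaffolds, counted from 1, and no gene, exon or UTR was assigned to them. The library name inside the file of seedlings replicate 2 is the one the labels give to seedlings replicate 1. Both are seedling libraries, and each file was used for the sample it was deposited under.

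From these counts, each distinct sequence was counted once per library whatever its number of genome matches. The totals were 185683 and 199408 reads for flowers replicates 1 and 2, and 30379 and 123634 for seedlings replicates 1 and 2. A count of 0 allows up to 3 reads, or 16.2, 15.0, 98.8 and 24.3 RPM (reads scaled to a total of 1000000 genome-matched reads) in the same order. Intervals for shares are 95% exact Clopper-Pearson intervals. Reads carry no molecular identifiers, so intervals and these limits cover counting error only.

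Reads were assigned to 71 families of known small RNAs (69 miRNA families and 2 families of trans-acting siRNAs) through a list of 94 mature *A. thaliana* sequences. That list was written from general knowledge before the data were examined and is not complete. A read of 19 to 25 nt belonged to a family if its first 18 nt equalled those of a listed sequence. Families with 10 or more reads over the 4 libraries were tested. Reads of 20 to 25 nt with 1 genome match were also counted in 1000-bp windows by their 5′ end, and single sequences of 19 to 25 nt were counted as such; both tables were filtered with filterByExpr. Flowers and seedlings were compared in each table with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are flowers over seedlings, and their standard error is the fold change divided by the square root of F. Length shares were taken over reads of 18 to 28 nt and compared with a two-sided exact permutation test. With 2 libraries against 2 its smallest possible p is 0.333, so no share could pass 0.05.

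Families were named by a rule set before the data were examined: the 10 with the highest mean RPM over the 4 libraries, up to 12 per direction among those past the threshold, and the most abundant member of each of 9 lists (conserved in flowering plants, Brassicaceae or Arabidopsis lineage, phase change, auxin signalling, organ patterning and growth, nutrient and copper response, small RNA pathway feedback, secondary siRNA triggers and products, pollen). Up to 4 windows and 4 sequences per direction were to be named among those past the threshold. The alternatives were DESeq2 size factors, all genome-matched reads as library size, DESeq2's Wald test (DESeq2 1.42.0), a replicate block, each library left out, other filters and read assignments, other windows and length classes, and other denominators.

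The tests were tried on simulated counts with the real means and library sizes. With a dispersion of 0.05, edgeR recovered 100% of 40 windows and of 59 sequences changed 16-fold, and 3 of 3 families. Of those changed 4-fold it recovered 63.4% of 41 windows, 78.0% of 59 sequences and 2 of 4 families, and of families changed 64-fold 2 of 3. False calls numbered 4 of 243 unchanged windows, 1 of 356 sequences and 0 of 21 families. With the dispersion fitted to the real libraries (1.67 for families, 1.57 for windows and 2.39 for sequences) it recovered 0 of those changed 16-fold or 64-fold in each table. Searches for phased windows, near matches of listed sequences and partner sequences near listed ones were chosen after seeing the data. The phasing search, tried on 500 random sets of each of 4 sizes, called 1.6% to 5.0% of them before adjustment. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.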

Results

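The series title names the evolution of MIRNA genes in *A. lyrata* and *A. thaliana*, and the labels divide the *A. lyrata* libraries into flowers and 14-day seedlings, so the comparison asked which small RNAs differ between these tissues. Depth ranged from 30379 reads in seedlings replicate 1 to 199408 in flowers replicate 2. The libraries differed in how often a sequence was read: 7.54 and 1.89 reads per distinct sequence in flowers replicates 1 and 2, and 3.67 and 4.05 in seedlings. Sequences seen once made up 18.6% of the distinct sequences of flowers replicate 1 and 75.9% of those of flowers replicate 2.

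Known miRNAs were read in both tissues. Of the 71 listed families, 37 had reads, and 13 of these had reads in all 4 libraries. In 35 of the 37, the most abundant variant was identical to a listed *A. thaliana* mature sequence. A family took only reads that share their first 18 nt with a listed sequence, so this compares the 3′ ends and leaves out variants within those 18 nt. The exceptions were miR827, a regulator of phosphate homeostasis, and siR255, a trans-acting siRNA. For miR827 the variant read was TTAGATGACCATCAACAAACG, which carried T21G relative to the listed sequence (positions count from 1 at the 5′ end), on the minus strand of scaffold 5 from 19566606 to 19566626, with 5 reads in flowers replicate 2 and 2 in seedlings replicate 2. The siR255 variant TTCTAAGTCCAACATAGCTAA carried G19T and T20A and lay on the minus strand of scaffold 4 from 19236705 to 19236725, with 12 reads in flowers replicate 2 and 9 in seedlings replicate 1. Conserved families accounted for most of the detections: 28 of 30 families conserved in flowering plants had reads, against 7 of 39 families of the Brassicaceae or Arabidopsis lineage. The other 32 lineage families had 0 reads under this exact-start rule, which does not show that they are absent.

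Listed miRNAs took a larger share of flower reads than of seedling reads in these libraries. The share was 3.54% (95% exact interval 3.45 to 3.62) and 9.36% (9.24 to 9.49) in the flower libraries, and 0.642% (0.555 to 0.738) and 0.851% (0.800 to 0.904) in the seedling libraries. The means were 6.45% ± 4.12 (SD, n = 2) and 0.746% ± 0.148 (SD, n = 2), a difference of 5.70 percentage points with an exact permutation p of 0.333, the smallest that 2 against 2 allows. Without flowers replicate 2 the difference was 2.79 points. In each flower library 1 family made up most of the share. The miR161 family took 2.40% of reads in flowers replicate 1 and 0.0522% in replicate 2. The miR159 family took 7.62% in flowers replicate 2 and 0.281% in replicate 1. The larger share is therefore not shown to hold for listed miRNAs in general.

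No single family passed the test between flowers and seedlings, and the libraries of one tissue differed widely from each other. In 16 of the 31 families tested, the flower libraries differed 10-fold or more or only one of them had reads. edgeR called 0 of 31 families (1 at an unadjusted p under 0.05), and DESeq2's Wald test called 0 (3 at an unadjusted p under 0.05). The smallest adjusted p from edgeR was 0.591. On simulated counts with the fitted dispersion of 1.67, edgeR recovered 0 families changed 16-fold or 64-fold, so 0 calls do not show that no family differs. The 2 most abundant families both differed widely between the flower libraries. The miR159 family, which targets MYB transcription factors, stood at 2811 and 76191 RPM in flowers and at 724 and 1205 RPM in seedlings, a fitted log2 fold change of 4.24 ± 3.19 (SE) that was 0.75 without flowers replicate 2. The miR161 family, which targets pentatricopeptide repeat genes, stood at 23955 and 522 RPM in flowers and at 1020 and 1359 RPM in seedlings, with a log2 fold change of 2.65 ± 2.62 (SE) that turned to −2.28 without flowers replicate 1. Thus flowers replicate 2 held 27.1 times more miR159 than replicate 1, and flowers replicate 1 held 45.9 times more miR161 than replicate 2. The main miR159 sequences TTTGGATTGAAGGGAGCTCTA and TTTGGATTGAAGGGAGCTCTT each matched 1 locus, on the minus strand of scaffold 2 from 15958642 to 15958662 and on the plus strand of scaffold 1 from 7594260 to 7594280. The main miR161 sequence TGAAAGTGACTACATCGGGGT matched scaffold 1 from 24491121 to 24491141 on the plus strand.

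**Figure D1:**
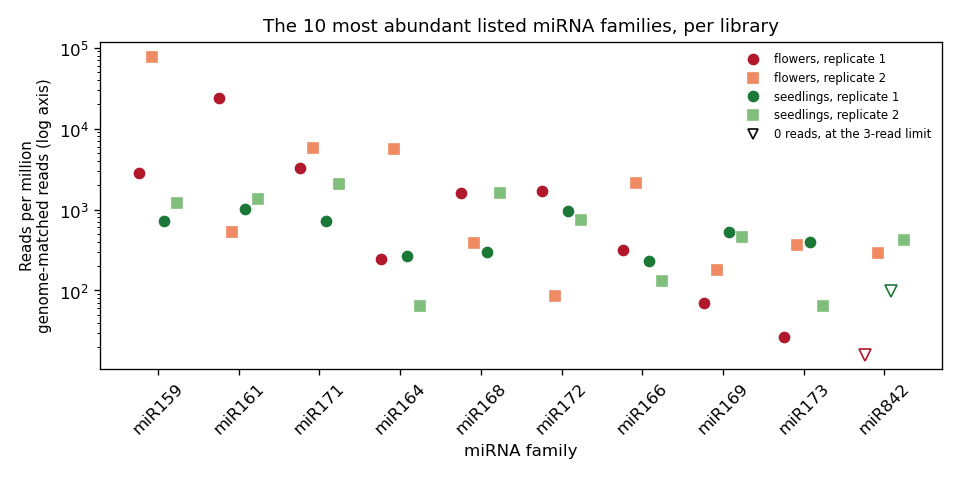
RPM, over all genome-matched reads (log axis), of the 10 most abundant listed families, with 1 point per library; open triangles mark 0 reads, drawn at the 3-read limit of the library. The flower libraries lie at 2811 and 76191 RPM for miR159 and at 23955 and 522 RPM for miR161, while miR169 lies higher in each seedling library than in each flower library.

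Over all 31 families tested, 18 were fitted higher in flowers and 13 lower, or 21 and 10 with all genome-matched reads as library size. Among families of organ patterning and growth, all 9 members were tested. Of these, 8 were fitted higher in flowers and 1 lower, the same split with all genome-matched reads as library size. Of the 9, 0 passed, also when adjusted over the list alone (smallest adjusted p 0.423, edgeR). With counts of 0 set at the 3-read limit of their library, each flower library lay above each seedling library in 4 of the 9 (miR159, miR165, miR166 and miR171). In 1 (miR396) each seedling library lay above each flower library, narrowly (48.53 RPM in seedlings replicate 2, 48.47 RPM in flowers replicate 1). Counting both directions, chance separates 2 against 2 in 33.3% of families. The miR171 family, which targets GRAS transcription factors of the shoot meristem, averaged 4527 ± 1810 RPM in flowers and 1389 ± 941 RPM in seedlings (SD, n = 2 each), with a fitted log2 fold change of 0.66 ± 2.24 (SE) that turned to −0.25 without seedlings replicate 1. The miR166 family, which targets class III HD-ZIP genes of organ polarity, stood at 312 and 2101 RPM in flowers (58 and 419 reads). In seedlings it stood at 230 and 129 RPM (7 and 16 reads). Its log2 fold change of 1.85 ± 2.19 (SE) ranged from 0.14 to 2.60 when single libraries were left out. Its close relative miR165 stood at 108 and 120 RPM in flowers and had 0 reads in seedlings replicate 1, which allows up to 98.8 RPM, and 1 read in seedlings replicate 2. The miR164 family, which limits the CUC genes of organ boundaries, stood at 248 and 5602 RPM in flowers and at 263 and 64.7 RPM in seedlings. TCP-targeting miR319 had 133 reads in flowers replicate 2 and 0 in each other library. A same-strand sequence within 300 bp of its scaffold 7 match from 21388977 had 7 and 1 reads in flowers and 0 and 2 in seedlings. Near its match from 7941312, another had 0 and 9 reads in flowers and 0 in each seedling library. The counts of 0 therefore do not show that miR319 was absent from those libraries. The member fitted lower was miR396, a regulator of growth-regulating factors, at 48.5 and 25.1 RPM in flowers and 198 and 48.5 RPM in seedlings.

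The conserved list as a whole gave 16 members fitted higher and 7 lower of 23 tested, with 0 passing over all tests or adjusted over the list alone (smallest adjusted p 0.539, edgeR). Outside the organ patterning list, no conserved member had each flower library above each seedling library once counts of 0 were set at the 3-read limit, which is highest in seedlings replicate 1. These fitted values move with the scaling: the median log2 fold change over the 31 families was 1.85 with TMM, 2.81 with DESeq2 size factors and 2.76 with all genome-matched reads as library size, so the values given here are relative to TMM on the listed families. The fitted values also move with the filter. With filterByExpr, which kept 16 families, 7 were fitted higher and 9 lower, with a median log2 fold change of −0.78. Of the Brassicaceae or Arabidopsis lineage, 6 members were tested, 2 fitted higher and 4 lower, or 3 and 3 with all genome-matched reads as library size, and 0 passed (smallest adjusted p over the list alone 0.665, edgeR). The least abundant of the 10 named families, miR842, belongs to this list; it had 58 and 52 reads in flowers replicate 2 and seedlings replicate 2 and 0 in the other libraries, which allows up to 16.2 RPM in flowers replicate 1 and 98.8 RPM in seedlings replicate 1.

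The main members of the phase-change and small RNA feedback lists, miR172 and miR168, differed in mean by less than the spread between libraries. In the phase-change list 2 of 3 members had reads and were tested, and 0 passed. Its main member miR172, which represses AP2-like genes, averaged 891 ± 1139 RPM in flowers and 845.3 ± 155 RPM in seedlings (SD, n = 2 each); its fitted log2 fold change of −0.55 ± 2.10 (SE) turned to 0.36 with DESeq2 size factors. SPL-targeting miR156 had 12 reads, all in flowers replicate 1 (64.6 RPM), while 0 reads in seedlings replicate 1 allow up to 98.8 RPM. A same-strand sequence within 300 bp of its scaffold 4 match had 0 and 15 reads in flowers and 0 and 7 in seedlings. The counts of 0 therefore do not show that miR156 was absent from those libraries. Of the feedback list, 3 of 4 members had reads, 2 were tested and 0 passed. AGO1-targeting miR168 averaged 990 ± 862 RPM in flowers and 957 ± 934 RPM in seedlings, with a fitted log2 fold change of −0.89 ± 2.12 (SE) that turned to 0.042 with all genome-matched reads as library size. AGO2-targeting miR403 had 3 and 38 reads in the flower libraries and 0 in each seedling library.

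Among nutrient and copper responsive families, 8 of 9 had reads and 5 were tested, of which 3 were fitted higher and 2 lower and 0 passed (smallest adjusted p over the list alone 0.360, edgeR). The most abundant, miR169, a regulator of NF-YA transcription factors, averaged 125 ± 78.2 RPM in flowers and 494 ± 46.4 RPM in seedlings (SD, n = 2 each), a log2 fold change of −2.87 ± 2.30 (SE) with an adjusted p of 0.608 from edgeR. It was lower in both flower libraries than in both seedling libraries. These values rest on few reads, 13 and 36 in flowers and 16 and 57 in seedlings. Laccase-targeting miR397 had 47 reads in flowers replicate 1, 1 in seedlings replicate 1 and 0 in the others.

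In the auxin list all 6 members had reads and were tested, 3 fitted higher and 3 lower, and 0 passed (smallest adjusted p over the list alone 0.218, edgeR). The tasiARF siRNAs, which target auxin response factor mRNAs, were the family with the smallest unadjusted edgeR p. They had 4 and 8 reads in the seedling libraries and 0 in both flower libraries, which allows up to 16.2 and 15.0 RPM there against 132 and 64.7 RPM in seedlings; the adjusted p was 0.591 (edgeR). A same-strand sequence within 300 bp of the tasiARF match on scaffold 3 had 11 and 7 reads in flowers and 0 and 10 in seedlings. The counts of 0 therefore do not show that this locus gave no small RNAs in flowers. The tasiARF trigger miR390 had 11 and 23 reads in flowers and 0 and 2 in seedlings. Of the list of siRNA triggers and products, 7 of 9 had reads and 6 were tested, 3 fitted higher and 3 lower, with 0 passing. The miR173 family, which triggers TAS1 and TAS2 siRNAs, averaged 197 ± 240 RPM in flowers and 230 ± 234 RPM in seedlings; its log2 fold change of −0.95 ± 2.34 (SE) turned to 0.41 with DESeq2 size factors. The pollen list held miR845 alone, with 0 reads of the listed sequence in each library.

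Reads of 21 nt, the usual length of miRNAs and trans-acting siRNAs, took a larger share in flowers, and reads of 24 nt, the usual length of heterochromatic siRNAs, a larger share in seedlings. The 21-nt share was 23.95% ± 0.960 in flowers and 13.6% ± 1.25 in seedlings (SD, n = 2 each), a difference of 10.4 points with an exact permutation p of 0.333. The 24-nt share was 35.4% ± 0.996 in flowers and 40.5% ± 5.03 in seedlings (SD, n = 2 each), a difference of −5.19 points with the same exact p. Counted as distinct sequences, the differences were 0.726 points for 21 nt and −0.149 points for 24 nt, and without seedlings replicate 1 the 24-nt difference was −1.64 points. Among 21-nt reads, 51.2% and 61.7% began with U in flowers and 43.6% and 38.6% in seedlings. Over distinct 21-nt sequences the means were 38.4% ± 0.533 in flowers and 41.0% ± 5.34 in seedlings (SD, n = 2 each), so the direction held for reads and not for distinct sequences. Fragments of the 3′ end of 5.8S ribosomal RNA, searched for after the long reads of the seedling libraries were seen and with a motif written from general knowledge, made up 1.53% and 0.856% of flower reads and 2.88% and 4.55% of seedling reads.

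**Figure D2:**
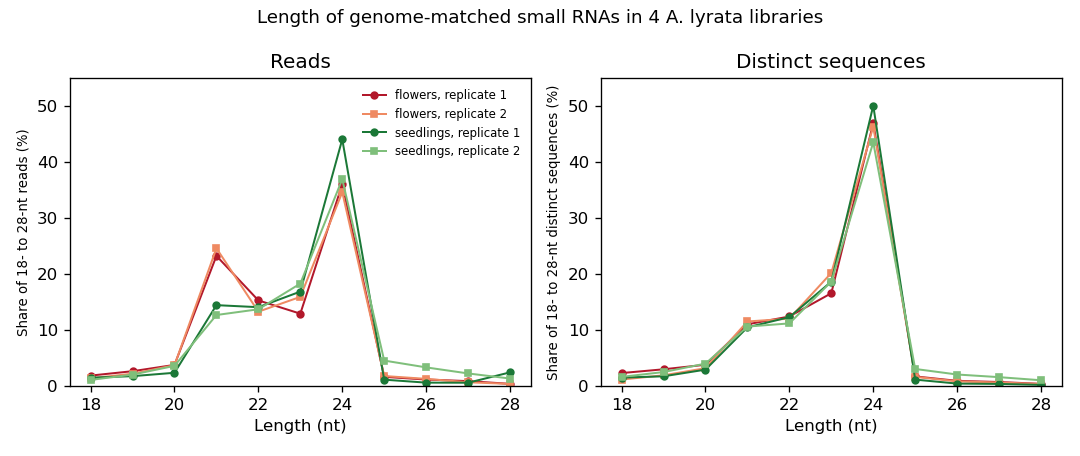
Share of reads (left) and of distinct sequences (right), in percent of those of 18 to 28 nt, against length in nt, with 1 line per library. By reads, the flower libraries stand at 23.3% and 24.6% for 21 nt and the seedling libraries at 14.5% and 12.7%; by distinct sequences the lines lie close together at 21 nt.

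Small RNA loci were compared in 364 windows, 17 with a listed miRNA and 347 without, and no window passed the test. edgeR called 0 windows (9 at an unadjusted p under 0.05) and DESeq2's Wald test 0 (14 at an unadjusted p under 0.05). Without flowers replicate 1, edgeR called 4 of 518 windows, all with higher fitted values in flowers; 3 of the 4 hold a listed miRNA (both miR159 loci and a miR164 locus). Windows led by 21-nt reads numbered 80, of which 56 were fitted higher in flowers and 24 lower, or 47 and 33 with all genome-matched reads as library size. The 174 windows led by 24-nt reads were fitted higher in 110 cases and lower in 64, or 77 and 97 on the other scaling, so their direction depended on it. Over all 364 windows, 234 were fitted higher and 130 lower, or 170 and 194 on the other scaling. The most abundant windows without a listed miRNA, chosen after their values were seen, were led by 21-nt or 22-nt reads. The first, on scaffold 6 from 1929001 to 1930000, stood at 77363 and 9754 RPM in flowers and at 6814 and 12205 RPM in seedlings, with seedlings replicate 2 above flowers replicate 2 and 22-nt reads its largest class (46.9% of its RPM). Its leading sequence TTCAATACCAGGGTGCTAAGTC, from 1929239 to 1929260 on the plus strand, had 4005 and 148 reads in flowers and 18 and 6 in seedlings. The window that holds siR255, on scaffold 4 from 19236001 to 19237000, averaged 11689 ± 5426 RPM in flowers and 8074 ± 4316 RPM in seedlings (SD, n = 2 each). A window on scaffold 8 from 22070001 to 22071000, with 99.9% of its RPM on the plus strand, stood at 14207 and 3420 RPM in flowers and at 724 and 1084 RPM in seedlings. Its leading sequence was CCTAGATGTGCTACATTACGA. Among the 8 most abundant of these windows, 19241001 to 19242000 on scaffold 4 had a lower mean in flowers (8355 against 8514 RPM). So did 23596001 to 23597000 on scaffold 7 (3395 against 4776 RPM) and 17801001 to 17802000 on scaffold 2 (2285 against 4870 RPM). The rest had higher means in flowers.

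Single sequences gave the same outcome. Of 533 sequences tested, 514 belonged to no listed family, and edgeR called 0 (9 at an unadjusted p under 0.05), as did DESeq2's Wald test (33 at an unadjusted p under 0.05). Sequences of 21 nt were fitted higher in flowers in 123 cases and lower in 44, or 92 and 75 with all genome-matched reads as library size. The 121 sequences of 24 nt were fitted higher in 75 and lower in 46, or 60 and 61 on the other scaling. Over all 533 sequences, 343 were fitted higher and 190 lower, or 263 and 270 on the other scaling.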

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

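The added alternatives (distinct sequences per window, and length shares without abundant 21-nt sequences, listed families or 5.8S fragments) were chosen after seeing the data. Of 35 alternatives for the counts of changed families, windows and sequences, 34 gave 0 calls. On simulated counts with the fitted dispersion, the main edgeR test recovered 0 of the features changed 16-fold or 64-fold. Agreement on 0 calls therefore does not show that the tissues are alike. Leaving out single libraries gave 0 to 4 windows: without flowers replicate 1, edgeR called 4, where the lone flower library is assumed to vary like the seedlings. Both miR159 loci (log2 fold changes 7.60 and 7.74) and the miR164 locus on scaffold 6 (8.61) were among them; the fourth lay on scaffold 2 from 8822001 to 8823000 (6.45). The range for families and for sequences was 0 to 0. With a replicate block, edgeR called 0 families, 0 windows and 0 sequences. Libraries with the same number deviated together across features with an r of 0.10 for families, 0.34 for windows and 0.14 for sequences, and nothing in the labels pairs them. With the block the common dispersion was 1.25 for families, 1.04 for windows and 2.15 for sequences. Without it, the values were 1.67, 1.57 and 2.39. An effect shared by libraries of the same number stays open.

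Of 120 values for the 10 named families under alternatives, 109 kept their sign and 11 did not; 0 passed the threshold. With DESeq2 size factors, edgeR's log2 fold change was 0.36 for miR172 and 0.41 for miR173, and DESeq2's own estimates were 0.36 and 0.41. With all genome-matched reads as library size it was 0.042 for miR168 and 0.077 for miR172. Leaving out single libraries gave ranges of −2.28 to 3.56 for miR161, −0.25 to 1.46 for miR171, −2.59 to 0.88 for miR168, −4.29 to 0.31 for miR172 and −8.26 to 6.97 for miR842. Without a change of sign they were 0.75 to 5.17 for miR159, 0.06 to 4.30 for miR164, 0.14 to 2.60 for miR166, −3.51 to −2.47 for miR169 and −3.53 to −0.042 for miR173. The cause was not tested. The length and miRNA shares kept their direction under each alternative: leaving out single libraries, the 21-nt difference ranged from 9.49 to 11.3 points, the 24-nt difference from −8.75 to −1.64 and the miRNA share difference from 2.79 to 8.62. Over distinct sequences the 24-nt difference was −0.149 points, without the abundant 21-nt sequences −1.81 and without the listed families −3.03, each with overlapping groups (exact permutation p of 1.0); for sequences with 1 genome match it was −10.7. A count of 0 in seedlings replicate 1, with 30379 reads, allows up to 98.8 RPM.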

Other observations

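The searches for near matches, partner sequences and phasing, and the tests on amplification, on abundant 21-nt sequences, on dilution and on chance similarity, were chosen after the results were seen; those on GC content and terminal nucleotides were written before.

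Relatives of listed miRNAs that had no reads were sought among sequences with 10 or more reads and up to 2 substitutions. Of 34 families searched, 2 had one. TTCTCGAGAAGGTGCATGAAC carried A6G relative to listed miR825 and had 595 and 305 reads in flowers and 2 and 87 in seedlings, from 6095752 to 6095772 on the plus strand of scaffold 4. CGGCTCTGATACCAGTTGATG carried A15G relative to listed miR845a, a miRNA known from pollen, and had 53 and 14 reads in the flower libraries and 0 in each seedling library, from 8114990 to 8115010 on the plus strand of scaffold 7. Over 100 shuffles of the searched sequences the most relatives found was 0, which argues only against chance similarity of random sequences with the same bases. Shuffles cannot tell a miRNA relative from a shared sequence of another kind. That the 2 sequences are *A. lyrata* members of miR825 and miR845 is a hypothesis. Hairpin folding was not tested, and no biological explanation was tested.

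At several loci another sequence on the same genomic strand, within 300 bp, had more reads over the 4 libraries than the listed mature sequence, as reads of the other hairpin arm would be placed. Beside a listed miR171b match on scaffold 2 (1951268 to 1951288), AGATATTGGTGCGGTTCAATC lay at 1951206 to 1951226 with 2650 and 0 reads in flowers and 6 and 0 in seedlings, against 52 and 27, and 3 and 2, for the listed sequence, which also matches scaffold 1. Beside miR391 on scaffold 8 (19524585 to 19524605), ACGGTATCTCTCCTACGTAGC had 491 and 288 reads in flowers and 4 and 196 in seedlings, against 0 and 63, and 0 and 3. Beside miR173 on scaffold 3, GATTCTCTGTGCAAGTGGAAG had 152 and 11 reads in flowers and 20 and 0 in seedlings, against 5 and 73, and 11 and 7, for the listed sequence, so it led in replicate 1 of each tissue and not in replicate 2.

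Of 80 windows with 10 or more positions of 21-nt reads, 3 held more positions in one 21-nt register than random placement gives, each with an adjusted p of 0.0445 by a hypergeometric test. They lay on scaffold 4 from 19241001 to 19242000 (18 of 139 positions), scaffold 1 from 26077001 to 26078000 (13 of 80) and scaffold 1 from 5319001 to 5320000 (6 of 17); random placement puts 4.76% in a register. The windows of the listed trans-acting siRNAs were not among them: that of siR255 on scaffold 4 (14 of 135 positions) and that of tasiARF on scaffold 3 (4 of 30) each had an adjusted p of 1.0. Before adjustment over windows, the siR255 window had a hypergeometric p of 0.0775. Its best register was the same in 4 libraries. That register held 16.5% and 52.1% of its 21-nt reads in flowers and 28.4% and 46.0% in seedlings. The register was chosen from these same data and the test counts positions, not reads, so it does not show that this window lacks phasing. The phased window on scaffold 4 from 19241001 averaged 8355 ± 4893 RPM in flowers and 8514 ± 4113 RPM in seedlings (SD, n = 2 each). Its register was also the best in 3 of the 4 libraries with 3 or more positions there. For the scaffold 1 windows this held in 4 of 4 libraries (from 26077001) and in 2 of 3 (from 5319001). The random sets tried held at most 100 positions, fewer than the 139 of the scaffold 4 window.

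Libraries of one tissue differed by an order of magnitude in single small RNAs, as for miR159 and miR161. Over 502 sequences, GC content had a Spearman rho of 0.0590 with the log2 ratio of the flower libraries. The first and last nucleotides accounted for 1.53% of the variance of that ratio. Over these sequences, neither a steady trend with GC content nor the terminal bases alone account for the spread between flower libraries. Other effects of GC content, and adaptor preferences beyond the terminal bases, were not tested. Amplification of few starting molecules stays open: over 50 windows the common dispersion was 0.679 for reads thinned to the totals of distinct sequences and 0.377 for distinct sequences, a measure that saturates. Differences between the sampled plants, and an effect shared by libraries of the same number, also stay open and were not tested. Across windows, the highest correlation of log2 CPM was between flowers replicate 2 and seedlings replicate 2 (r = 0.72), above those within flowers (0.42) and within seedlings (0.28). Across sequences that pair of second replicates was again highest (r = 0.27), above those within flowers (0.22) and within seedlings (−0.13). Across families the highest was within seedlings (r = 0.69), and that pair of second replicates stood at 0.59.

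The larger 21-nt share in flowers could come from a few abundant sequences. Without the 10 most abundant 21-nt sequences of each library, flowers stood at 13.9% ± 1.14 and seedlings at 10.9% ± 0.468 (SD, n = 2 each), a difference of 3.02 points against 10.4 with them, so these sequences make up most of the difference but not all of it. Dilution of the seedling libraries by RNA fragments of other lengths would leave the ratio of 21-nt to 24-nt reads equal; it was 0.678 ± 0.0463 in flowers and 0.336 ± 0.0109 in seedlings (SD, n = 2 each), a difference of 0.343. A difference between the tissues stays open: the exact test could not pass with 2 libraries each, so its p says nothing for or against it.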
